A study of Mus musculus with 6 samples.

How the data were processed

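Small RNA libraries from 6 samples of mouse iBN cells, 3 induced and 3 uninduced, were analysed from the deposited tables. Per the labels' protocols, the cells carried a PU.1-inducible system and grew in suspension with GM-CSF and fetal bovine serum, RNA was purified with the miRNeasy kit, and libraries were made from total RNA with the Illumina TruSeq small RNA kit, size-selected and sequenced as single reads on a HiSeq. Per the submitters' processing notes, Trim Galore 0.4.0 and DESeq2 (listed as version 2.1.8.0) were used with the mm10 build, and the series' design text states that reads were aligned to miRBase. The read counter, the miRBase release, the treatment of reads with several matches and the use of strand are not given in the sources used here. No molecular identifiers are described, so PCR copies cannot be told from separate molecules.

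The authors deposited raw read counts per library, with the unit named in the column headers of the file, in a table of 2061 entries, each a mature microRNA with one of its precursors. The table holds 1915 distinct mature names, of which 83 have several entries (229 in all). Of the 39 such names with at least 500 reads, 30 had a lowest entry within 1% of the highest, so the same reads were entered for several precursors. The entry with the highest total was kept for each name, which left out 17.5% of the table's total, and the sum and the lowest entry were tried as alternatives. The authors also deposited normalized values in CPM, which equal the counts divided by the sum of all entries of a library and scaled to CPM, within 0.005. They were used only in one alternative. Of the names with at least 100 reads, 22 pairs had counts within 1% of each other in every library, and microRNAs in such pairs were treated as sharing reads. After this step the libraries held 8697384 to 13946613 reads, and the 5 most abundant microRNAs took 47.4% ± 3.02 of them in the uninduced and 47.1% ± 3.18 in the induced libraries (SD, n = 3 each). No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom of 110 or more), so none was deposited under several names. Each library was taken as 1 replicate, as the labels list them, although the labels do not say that they are separate cultures.

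Differences were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group, glmQLFit with robust estimation and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05. The filter kept 525 microRNAs, which hold 99.987% of the reads, and left 1390 names untested. Fold changes are induced over uninduced, and the model used the group alone. CPM values in the text are TMM-scaled. For microRNAs with 3 or fewer uninduced reads, the ratio of summed reads per total was given with an exact conditional 95% interval, and with 0 reads a bound on a floor of 3 counts over the group. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 15 lists with at least 3 tested members, with an estimated correlation and fry as alternatives. The estimated correlation kept 0 of the 5 calls made with the preset one. It was 0.217 for the stromal and 0.037 for the miR-221 and miR-222 list. For the epithelial (-0.062), lymphoid (-0.024) and miR-17 (0.006) lists it lay below the preset value. A higher correlation between members therefore cannot account for the loss of those calls. The 12 microRNA lists and 8 lists of markers of other cell types were written before the data were examined, as were the tests and the rule for named microRNAs. The microRNA lists are those reported as PU.1-induced, macrophage-associated, granulocyte and C/EBP-associated and progenitor-associated, the miR-17 family clusters, the let-7, miR-15 and miR-16, miR-29, miR-30 and miR-34 families, miR-221 and miR-222, and the Dlk1-Dio3 cluster. The marker lists are erythroid, lymphoid, embryonic stem, epithelial, stromal, muscle, liver and neural.

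The rule for named microRNAs takes up to 10 microRNAs per direction with the largest log2 fold change among those past the threshold, with at least 10 CPM on average and separate groups, the 5 most abundant, the more abundant arm of 20 microRNAs fixed in advance, and up to 4 of the most abundant tested members of a list as examples. MicroRNAs outside this rule, including those named because they were the members of a list that passed or lay in a named cluster, were chosen after their values were seen. Hairpin positions were taken from the RefSeq annotation of GRCm38 and their place in genes from GENCODE, matched by name; mm10 is the same assembly.

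The labels number the libraries of both groups as trials 1, 2 and 3. After subtraction of the group means, the log2 CPM of libraries of the same trial correlated across microRNAs by 0.33, 0.45 and 0.53, each library correlating best with the library of its own trial, so with every pair over 0.1 the trials were taken to pair the samples, from the numbers in the labels and this check. The first principal component (60.9% of the variance) separated the groups and the second (20.3%) set trial 3 apart from the others. The fit with the trial as a replicate block was an alternative fixed beforehand. Other alternatives fixed in the same way were DESeq2 1.42.0, limma-voom, other scaling factors, no filter and a filter of 10 CPM in 3 libraries, the arms of a hairpin summed, limma-trend on the deposited normalized values plus 1, a test against a 1.5-fold change, and each library left out in turn. The alternatives on repeated entries, DESeq2 with the block, camera with the block and an estimated correlation, fry with the block, and both libraries of a trial left out were chosen after seeing the data.

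The edgeR and camera steps were tested on simulated data, drawn from the means and library sizes of these samples with 200 changed microRNAs, 193 of them left after the filter. For the comparison of induced with uninduced cells, the unblocked fit (509 microRNAs) recovered 47.8% of 1.5-fold, 93.8% of 2-fold and 100% of 4-fold changes, and 3.8% of its calls were unchanged microRNAs. The blocked fit, on 506 microRNAs simulated with an assumed trial effect (SD 0.2 on the log2 scale) and with the dispersion divided by 4, recovered 83.3%, 93.9% and 100%, with 1.1% of calls unchanged, values that hold for those assumed settings. With camera, 5% of 200 unchanged lists had an unadjusted p under 0.05. These were random lists of microRNAs simulated independently of each other. The share need not hold for lists whose members move together, such as the stromal list with an estimated correlation of 0.217.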

Results

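Small RNAs were sequenced from mouse iBN cells, a suspension line that the labels describe as granulocyte-macrophage progenitor cells and that carries an inducible form of PU.1, the myeloid transcription factor encoded by Spi1. Cells left uninduced (n = 3 libraries) were compared with cells kept in 1000 ng/ml doxycycline for 72 hours (n = 3 libraries), each group holding trials 1, 2 and 3. The title of the series places the comparison in the study of how the dose of PU.1 acts in myeloid differentiation. The level of PU.1 itself was not measured by this assay, and no library of doxycycline-treated cells without the inducible gene was analysed here. With 1 entry kept per mature microRNA, the uninduced libraries held 9162211, 8697384 and 11714847 reads and the induced libraries 11379870, 9089319 and 13946613 reads. At these totals, a count of 0 in 1 library allowed up to 0.215 to 0.345 CPM (counts scaled to library size), a limit that, like the count intervals given here, covers counting error only because the labels describe no molecular identifiers. The labels do not say that the trials were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

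A few microRNAs that were nearly undetected in uninduced cells were present after induction. miR-342-3p, which is processed from an intron of Evl and is a reported PU.1 target, rose from 1 read in all uninduced libraries together to 670 reads in the induced ones, a ratio of 568 (95% exact interval 102 to 22450). Its level in induced cells was 19.4 CPM ± 0.38 (SD, n = 3), against 0.04 CPM ± 0.06 (SD, n = 3) without doxycycline. miR-511-3p, from an intron of the macrophage mannose receptor gene Mrc1, rose from 3 reads to 318, a ratio of 89.8 (95% exact interval 30.4 to 438). miR-708-3p and miR-10b-5p fell the most among microRNAs that passed the test with at least 10 CPM and separate groups, by 2.64 (SE 0.33, n = 3 per group) and 2.22 (SE 0.16, n = 3 per group) on the log2 scale. Of 525 microRNAs tested, 32 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 18 were higher and 14 lower in induced cells.

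All 32 moved in the same direction in each of the 3 trials, and 21 of them changed at least 2-fold. They were selected in these same libraries, so the agreement between trials is no separate support. An unadjusted p under 0.05 was reached by 109 microRNAs, and for 145 microRNAs (27.6%) the CPM of the groups did not overlap. Chance gives 10% for exchangeable libraries, which libraries paired by trial are not. With the trial as a block, the same test passed 114 microRNAs, 56 higher and 58 lower, including all 32. The unblocked count fell to 16 without induced replicate 1, 14 without induced replicate 2, 12 without uninduced replicate 1 and 17 without uninduced replicate 2. The blocked count was 66, 60 and 12 when both libraries of trials 1, 2 and 3 were left out. Without trial 3 the unblocked count was 38.

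Of the tested microRNAs, the other 3 with 0 or 1 uninduced read were also higher in induced cells, a direction fixed by the filter. It keeps a microRNA this rare without induction only if its reads are high enough in the induced libraries. miR-342-5p, the other arm of the miR-342 hairpin, had 0 reads uninduced and 45 induced and was at least 12.7-fold higher, taking 3 counts over the uninduced group as the floor. miR-218-5p, made from hairpins in introns of Slit2 and Slit3, had 0 and 58 reads and was at least 16.4-fold higher on the same floor. miR-511-5p had 1 and 67 reads, a ratio of 56.8 (95% exact interval 9.84 to 2274). The edgeR adjusted p was 1.3e-06 for miR-342-3p, 1.8e-05 for miR-511-3p, 9.96e-04 for miR-511-5p, 0.0014 for miR-218-5p and 0.0020 for miR-342-5p. The 2 arms of miR-511, miR-342-5p and miR-218-5p were chosen after their values were seen. In GRCm38, the mm10 assembly, the miR-342 hairpin lies on chromosome 12 from 108658620 to 108658718 and the miR-511 hairpin on chromosome 2 from 14261003 to 14261081, each on the strand of the gene that contains it.

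**Figure D1:**
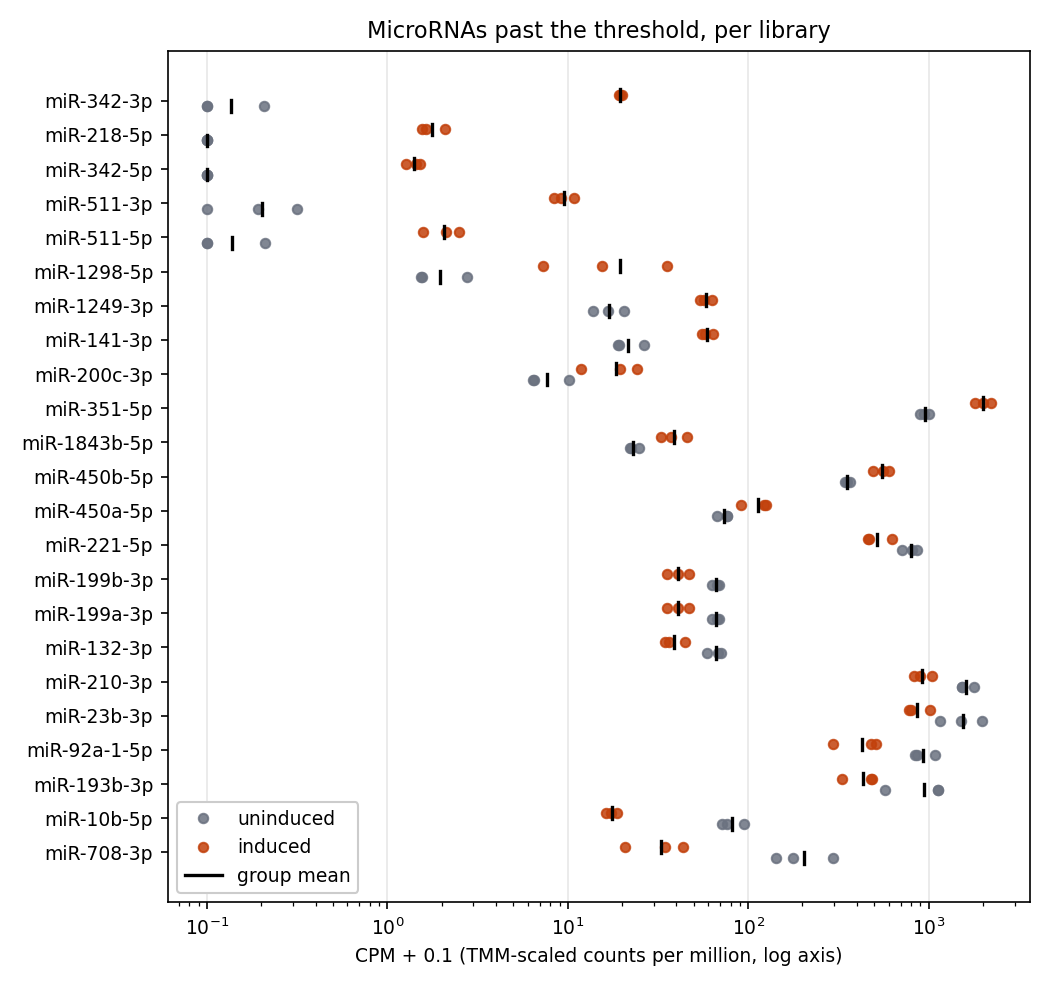
CPM (TMM-scaled, plus 0.1, on a log axis) of microRNAs past the threshold in each of the 3 uninduced (grey) and 3 induced (orange) libraries, with black bars at the group means. Every microRNA drawn has separate groups, which was a condition of the choice for those of at least 10 CPM. miR-342-3p goes from a mean of 0.04 to 19.4 CPM.

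Among microRNAs of at least 10 CPM, 8 passed the test upward with separate groups. miR-1298-5p, from an intron of the serotonin receptor gene Htr2c (chromosome X, 147064905 to 147065002), increased by 3.37 on the log2 scale (SE 0.65, edgeR adjusted p = 0.032), with 35.3, 15.4 and 7.20 CPM in the induced and 2.67, 1.45 and 1.47 CPM in the uninduced libraries of trials 1, 2 and 3. miR-1249-3p (chromosome 15, 84951526 to 84951623, overlapping an exon of 5031439G07Rik) went from 16.9 CPM ± 3.33 to 58.0 CPM ± 4.81 (SD, n = 3 each), a log2 change of 1.78 (SE 0.18). miR-141-3p and miR-200c-3p, members of the epithelial miR-200 family that lie next to each other on chromosome 6 between 124717914 and 124718390, rose by 1.45 (SE 0.17) and 1.28 (SE 0.29). miR-1843b-5p, from an intron of Cop1, rose by 0.74 (SE 0.17). The other 3 came from one stretch of chromosome X. miR-351-5p doubled from 951 CPM ± 55.1 to 2004 CPM ± 203 (SD, n = 3 each; log2 change 1.08, SE 0.12, edgeR adjusted p = 7.4e-04), and miR-450b-5p and miR-450a-5p rose by 0.64 (SE 0.13) and 0.62 (SE 0.16). miR-450a-5p has 2 hairpins there, so its reads cannot be assigned to one of them.

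Of the 10 microRNAs that fell under the same rule, miR-708-3p (chromosome 7, 96249424 to 96249532, in an intron of Tenm4) went from 205 CPM ± 79.5 to 32.9 CPM ± 11.6 and miR-10b-5p (chromosome 2, 74726070 to 74726137, among the Hoxd genes) from 80.8 CPM ± 12.6 to 17.4 CPM ± 1.26 (SD, n = 3 each). Their edgeR adjusted p-values were 9.96e-04 and 2.4e-05. miR-193b-3p fell by 1.12 (SE 0.26), and so did miR-92a-1-5p (SE 0.21), the minor arm of a hairpin in the miR-17 cluster transcript Mir17hg. miR-23b-3p fell by 0.84 (SE 0.20), miR-210-3p, the hypoxia-induced microRNA, by 0.81 (SE 0.13), miR-132-3p by 0.78 (SE 0.16) and miR-221-5p by 0.62 (SE 0.15). The other arm of the miR-210 hairpin, miR-210-5p, averaged 190 CPM and had a log2 change of -0.01. The remaining 2 entries, miR-199a-3p and miR-199b-3p, fell by 0.69 each (SE 0.15), but their counts were within 1% of each other in every library, so they share their reads and stand for 1 measurement of uncertain origin.

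Of all 32 called microRNAs, 12 passed in each of the 6 unblocked fits that left out 1 library and 20 lost the call in at least 1. Of the 23 named so far, 11 passed in all 6, namely both arms of miR-342 and of miR-511, miR-218-5p, miR-1249-3p, miR-141-3p, miR-351-5p, miR-708-3p, miR-10b-5p and miR-210-3p. The other 12 lost the call in at least 1 such fit, with edgeR adjusted p up to 0.121 for miR-1298-5p without uninduced replicate 3, 0.122 for miR-132-3p, 0.166 for both miR-199 entries and 0.216 for miR-221-5p without induced replicate 1, 0.125 for miR-1843b-5p without induced replicate 2, and 0.118 for miR-92a-1-5p, 0.123 for miR-450b-5p, 0.141 for miR-23b-3p, 0.173 for miR-193b-3p, 0.183 for miR-450a-5p and 0.189 for miR-200c-3p without uninduced replicate 1. Apart from miR-92a-1-5p, each lost the call in several fits, mostly those without replicate 1 or 2 of a group. miR-193b-3p and miR-23b-3p also lost it without induced replicate 3, and miR-1298-5p, miR-221-5p and miR-450a-5p without uninduced replicate 3. These fits did not use the pairing by trial. With the trial as a block, 30, 27 and 9 of the 32 passed when both libraries of trials 1, 2 and 3 were left out.

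**Figure D2:**
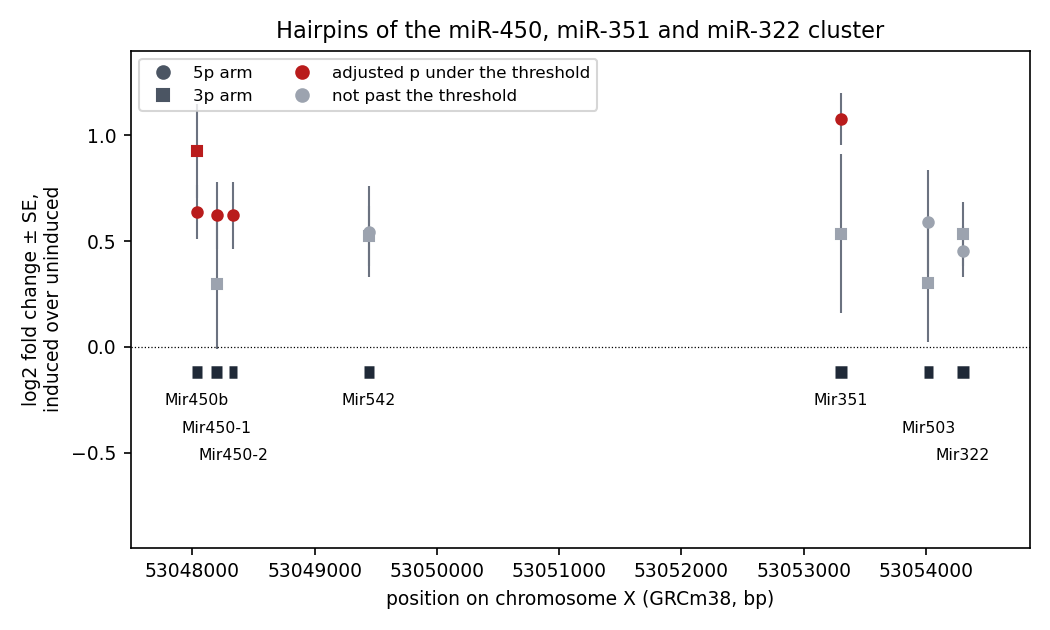
Log2 fold change (induced over uninduced, bars give the SE) of each tested arm of the hairpins between 53047997 and 53054349 on chromosome X in GRCm38, against hairpin position; circles are 5p arms, squares 3p arms, and red marks adjusted p under 0.05. Every arm drawn has a positive value, and miR-351-5p, at 1.08, is the largest of them; miR-450a-5p is drawn at both of its hairpins.

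The bulk of the microRNA pool did not pass the test. miR-146b-5p alone made up 14.5% of the reads and averaged 142613 CPM ± 21777 uninduced and 146970 CPM ± 16670 induced (SD, n = 3 each), a log2 change of 0.04 (SE 0.13). The next in abundance, miR-191-5p, miR-92a-3p, miR-148a-3p and the haematopoietic miR-142a-5p, had log2 changes of -0.07 (SE 0.14), 0.01 (SE 0.09), -0.20 (SE 0.13) and 0.05 (SE 0.16). miR-92a-3p has 2 precursors, whose shares of its reads are not known. For these 5 the edgeR adjusted p ranged from 0.416 to 0.977.

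Several microRNAs with a known place in myeloid cells were also followed whatever their result. miR-223-3p, the granulocytic microRNA, had 6513 CPM ± 2093 uninduced and 5564 CPM ± 2407 induced (SD, n = 3 each; log2 change -0.23, SE 0.39, edgeR adjusted p = 0.808), with trial 3 lowest in both groups at 4321 and 2799 CPM. miR-155-5p, an inflammatory microRNA, had a log2 change of -0.20 (SE 0.13), and miR-338-3p one of 0.01 (SE 0.13). miR-21a-5p went from 11859 CPM ± 2052 to 17261 CPM ± 2718 (SD, n = 3 each; log2 change 0.54, SE 0.16, edgeR adjusted p = 0.075). miR-27a-3p, miR-29b-3p, miR-17-5p, miR-130a-3p and miR-222-3p had log2 changes between -0.23 and -0.17, and miR-126a-5p and the lymphocyte microRNA miR-150-5p had 0.02 (SE 0.24) and 0.16 (SE 0.23), none of them past the test. miR-196b-5p was too rare to test, with 3, 4 and 5 reads uninduced and 10, 3 and 5 induced.

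For 6 of these followed microRNAs the call depended on the block. miR-146a-5p, a brake on inflammatory signalling, had 4.43 CPM ± 0.18 uninduced and 6.55 CPM ± 0.28 induced (SD, n = 3 each), a log2 change of 0.56 (SE 0.19) with an edgeR adjusted p of 0.123 unblocked and 0.037 blocked. The edgeR adjusted p went from 0.171 to 0.037 with the block for miR-22-3p (log2 change 0.28, SE 0.11), from 0.056 to 0.0034 for miR-322-5p (0.45, SE 0.12) and from 0.320 to 0.0069 for miR-125a-5p (0.52, SE 0.27). For the negative ones it went from 0.051 to 5.8e-04 for miR-221-3p (-0.64, SE 0.17) and from 0.211 to 0.025 for miR-181a-5p (-0.29, SE 0.12).

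The microRNAs were next grouped by 20 lists fixed in advance, 15 of which had at least 3 tested members and were compared with all other microRNAs by camera with a preset correlation of 0.01. The list of microRNAs reported as PU.1-induced did not pass camera, so it was not shown to move further in one direction than other microRNAs. Camera compares shifts in one direction, so a list whose members move both ways may fail it. Of the 22 tested members of the PU.1 list 2 rose, both arms of miR-342, 0 fell and 20 did not pass. Adjusted over the list alone 4 were higher. An unadjusted edgeR p under 0.05 was reached by 8 of the 22, against 109 of all 525 tested microRNAs. With the block 7 were higher and 2 lower. Members such as miR-23a-3p (log2 change -0.11, SE 0.12), miR-27a-3p (-0.17, SE 0.13) and miR-503-5p (0.59, SE 0.25) did not pass. The list's median log2 change was -0.02, its mean 0.71 (0.57 with miR-342-5p at its bound), and its camera adjusted p 0.209. Among 18 tested macrophage-associated microRNAs, 4 rose, the arms of miR-342 and miR-511, and 1 fell, miR-132-3p, known as an immune-response microRNA. Adjusted over the list alone 6 were higher and 2 lower, and with the block 5 were higher and 5 lower. An unadjusted edgeR p under 0.05 was reached by 11 of the 18. The median was -0.08 and the mean 1.35 (1.18 with miR-342-5p at its bound), and the camera adjusted p was 0.239. fry, which asks only whether the members move on balance one way, gave an adjusted p of 0.0059 for the PU.1 list and 0.0010 for the macrophage list, both upward. With the block, fry's adjusted p was 0.056 for the PU.1 list, which then no longer passed, and 0.017 for the macrophage list. Both lists count the arms of miR-342 as separate members, and the macrophage list also those of miR-511. With so few uninduced reads, the filter keeps these arms only if they are high in the induced libraries. Their upward direction was thus fixed by the filter, and they lend the upward fry results no separate support.

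**Figure D3:**
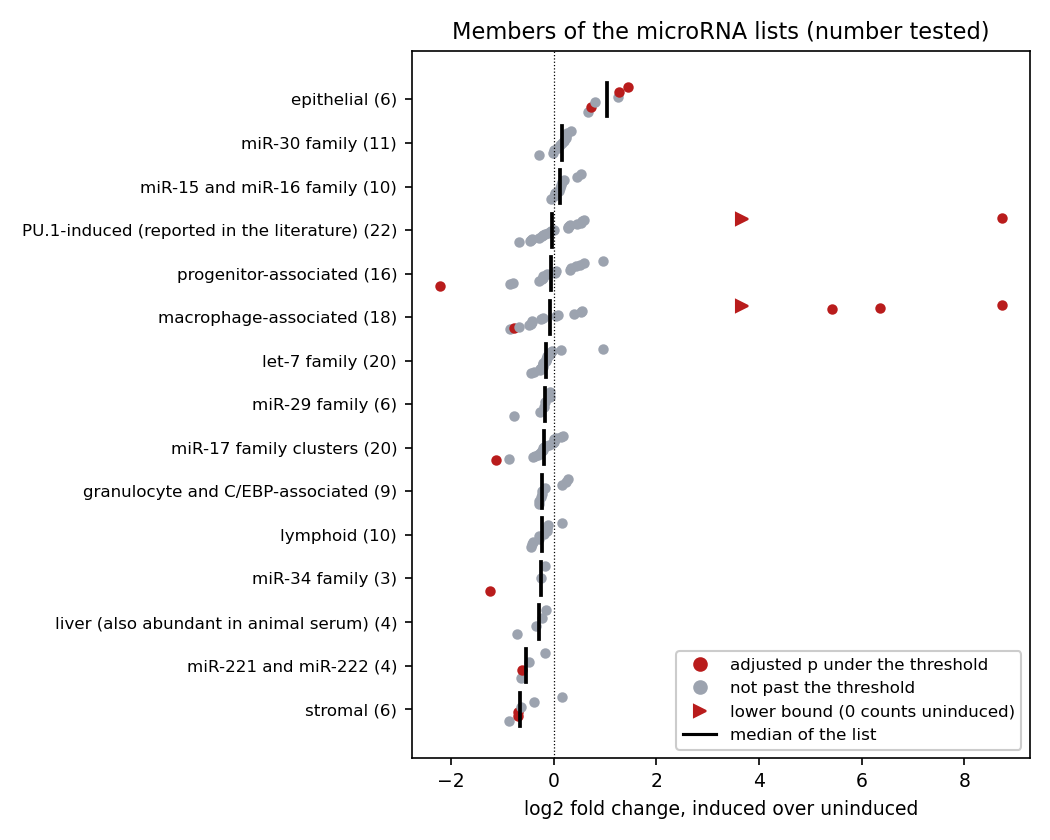
Log2 fold change (induced over uninduced) of each tested member of the 15 lists, with the number tested in brackets; red marks adjusted p under 0.05, grey the rest, triangles a lower bound for a member with 0 uninduced reads, and black bars the list medians. The medians run from -0.66 for the stromal list to 1.03 for the epithelial list, and the far right points are the arms of miR-342 and miR-511.

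Of the 5 lists that passed camera, the epithelial markers were the only one that was higher. Of 6 tested members 3 rose, miR-141-3p, miR-200c-3p and miR-200b-3p (0.73, SE 0.19), whose call was lost in each of the 6 fits that left out 1 library (edgeR adjusted p up to 0.189 without uninduced replicate 1), and 5 were higher adjusted over the list alone, while DESeq2 passed 2 and limma-voom 1 of the 6. Their summed level went from 37.8 CPM ± 3.84 to 92.1 CPM ± 10.2 (SD, n = 3 each). The camera adjusted p was 2.3e-04, and adjusted p = 0.166 with an estimated correlation. The other 4 lists were lower. Of 6 tested stromal markers 2 fell, the entries miR-199a-3p and miR-199b-3p that share their reads, and 3 were lower adjusted over the list alone, while miR-143-3p had -0.39 (SE 0.18). The block raised the number lower to 5. The stromal camera adjusted p was 0.0056, and adjusted p = 0.220 with an estimated correlation, both with the shared reads of miR-199a-3p and miR-199b-3p counted as 2 members. In the miR-17 family clusters, which promote proliferation, 1 of 20 tested members fell, miR-92a-1-5p, also the 1 lower adjusted over the list alone, and 5 were lower with the block. miR-17-5p had -0.22 (SE 0.11), and miR-25-3p, from the related cluster inside Mcm7, 0.00 (SE 0.14). The camera adjusted p was 0.041, and adjusted p = 0.220 with an estimated correlation.

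Of the 4 arms of miR-221 and miR-222, which target the receptor Kit, 1 fell over all tested, miR-221-5p, 2 adjusted over the list alone and 3 with the block, while limma-voom passed 0 of them. The camera adjusted p was 0.041, and adjusted p = 0.220 with an estimated correlation. Of the 10 tested lymphoid markers 0 passed in edgeR, over all tested or adjusted over the list alone, 0 in DESeq2 or limma-voom, and 2 at an unadjusted edgeR p under 0.05. With the block 2 were lower, miR-181a-5p and miR-181a-1-3p (-0.43, SE 0.13). Their camera adjusted p was 0.046, and adjusted p = 0.220 with an estimated correlation. The calls of the epithelial and stromal lists held in each of the 6 fits that left out 1 library. The lymphoid, miR-221 and miR-222, and miR-17 calls were lost in 5, 4 and 3 of these, with camera adjusted p up to 0.111 without uninduced replicate 2, 0.0645 and 0.0616 without induced replicate 2. The lymphoid call held only without induced replicate 3, the miR-221 and miR-222 call was lost without replicates 1 or 2 of the induced or 1 or 3 of the uninduced group, and the miR-17 call without induced replicate 2 or uninduced replicates 1 or 3.

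The remaining lists did not pass camera without the block. In the let-7 family, which restrains proliferation, 0 of 20 tested members passed in edgeR over all tested or adjusted over the list alone, and 0 in DESeq2 or limma-voom. At an unadjusted edgeR p under 0.05 there were 3, with let-7a-5p at -0.44 (SE 0.11, edgeR adjusted p = 0.0505) and let-7i-5p at -0.15 (SE 0.09). With the block 3 were lower, and the camera adjusted p went from 0.052 to 0.020, or adjusted p = 0.474 with an estimated correlation. In this list let-7a-1-3p and let-7c-2-3p, with counts within 1% of each other in every library, are 1 measurement counted as 2 members. Of 4 liver markers, which are also abundant in animal serum such as that in the medium, 0 passed in edgeR over all tested or adjusted over the list alone and 0 in DESeq2 or limma-voom, against 2 at an unadjusted edgeR p under 0.05 and 2 lower with the block. Their camera adjusted p went from 0.075 to 0.040 with the block, or adjusted p = 0.474 with an estimated correlation. Of 16 tested progenitor-associated microRNAs 1 fell, miR-10b-5p, which was also the 1 lower adjusted over the list alone, and the camera adjusted p was 0.242. The block gave 1 higher, miR-125a-5p, and 2 lower.

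Of the 3 tested miR-34 family members 1 fell, miR-34c-5p (-1.24, SE 0.29), as it did adjusted over the list alone. Its call held without uninduced replicate 3 and was lost without each of the other libraries, with edgeR adjusted p up to 0.151 without induced replicate 2. In the next 6 lists no member passed edgeR over all tested. In the granulocyte and C/EBP-associated list of 9, 0 also passed adjusted over the list alone, in DESeq2, in limma-voom or at an unadjusted edgeR p under 0.05, and 1 was higher with the block, miR-182-5p. In the miR-15 and miR-16 family of 10, 2 were higher adjusted over the list alone, both arms of miR-322, and these were also the 2 that passed with the block and the 2 at an unadjusted edgeR p under 0.05, while DESeq2 passed 1 and limma-voom 0. In the miR-30 family of 11, 0 passed adjusted over the list alone, in DESeq2 or in limma-voom and 1 at an unadjusted edgeR p under 0.05, while 2 were higher with the block, miR-30b-5p and miR-30d-5p. In the miR-29 family of 6, 0 passed adjusted over the list alone, in DESeq2, in limma-voom or with the block, and 1 at an unadjusted edgeR p under 0.05. The camera adjusted p was 0.112 for the miR-34, 0.379 for the granulocyte, 0.199 for the miR-15 and miR-16, 0.268 for the miR-30 and 0.138 for the miR-29 list. The erythroid and neural lists had 2 tested members each, such as miR-486a-5p (0.34, SE 0.18) and miR-219a-5p (-0.11, SE 0.18), of which 0 passed adjusted over the list alone, in DESeq2, in limma-voom or at an unadjusted edgeR p under 0.05, although both erythroid members were higher adjusted over the list alone in the blocked fit. These, miR-486a-5p and miR-486b-5p, had counts within 1% of each other in every library and stand for 1 measurement. The Dlk1-Dio3 cluster, embryonic stem and muscle lists had 0 tested members.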

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

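The fits that left out a trial, the blocked DESeq2 fit, camera with the block and an estimated correlation, fry with the block, and the sum or lowest of repeated entries were chosen only after the data were seen. The count of 32 microRNAs became 114 with the replicate block, 74 with DESeq2 and the block, 20 with limma-voom, 14 with the stricter filter (324 tested) and 12 against a 1.5-fold change, and ranged from 12 (without uninduced replicate 1) to 41 (without uninduced replicate 3) when 1 library was left out. With trials 1 or 2 left out it was 11 each, or 66 and 60 with the block, where 30 and 27 of the 32 remained. Without trial 3 it was 38, or 12 with the block, where 9 of the 32 remained. These fits rest on fewer samples. Other fits gave 22 to 48, the most without a filter, of which 30 were among the 32. The count of 5 lists became 0 with an estimated correlation, with or without the block, 7 with the block in camera or with fry, 3 with fry and the block (epithelial, macrophage-associated and liver), 1, 3 and 6 without trials 1, 2 and 3, and 2 to 5 with 1 library left out. Apart from the 6 microRNAs and 2 lists named in the report, whose calls were gained, the block changed no other call among the 45 named microRNAs in edgeR and the 15 lists in camera, although it raised several counts within lists. Sign changes occurred only in 7 named microRNAs without a call, and their cause was not tested. With 1 library left out, the log2 change ranged from -0.076 to 0.164 for miR-146b-5p, -0.211 to 0.072 for miR-191-5p, -0.056 to 0.045 for miR-92a-3p, -0.14 to 0.205 for miR-142a-5p, -0.469 to 0.054 for miR-223-3p, -0.071 to 0.077 for miR-338-3p and -0.287 to 0.276 for miR-126a-5p. miR-146b-5p had -0.062 without trial 2 and -0.065 with the block as well. miR-92a-3p had -0.013 with DESeq2 and with its size factors in edgeR, -0.010 with DESeq2 and the block, -0.037 with arms summed, -0.058 with entries summed, -0.186 with the lowest entry, and -0.062 without trial 3, blocked or not. miR-338-3p had -0.005 with DESeq2, with its size factors and without trial 2, -0.006 with DESeq2 and the block, and -0.003 without trial 2 and with the block. miR-126a-5p had -0.002 with DESeq2 and the block, -0.003 without trial 2 with the block, and -0.012 and -0.011 without trial 3, unblocked and blocked. Of all 1203 comparisons of a named microRNA with an alternative, 1008 kept direction and side of the threshold, 132 lost and 28 gained a call and 35 changed sign, and for the lists these were 184 kept, 32 lost and 9 gained. Depth limits the microRNAs with 3 or fewer uninduced reads, whose ratios are known only within the intervals given.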

Other observations

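The microRNAs and hairpin groups described in this part, the arm comparison, and the tests on neighbouring hairpins and on epithelial markers were chosen only after the results were seen, and the reading of the sample splits was set down after their counts were seen. Beside miR-1298-5p, the other arm of its hairpin and 3 further hairpins in introns of Htr2c, on the same strand of chromosome X, had more pooled reads in induced libraries, a difference not tested between groups. miR-448-3p (147158210 to 147158321) had 6 reads in the uninduced and 97 in the induced libraries, a ratio of 13.9 (95% exact interval 6.16 to 38.8, counting error only), miR-1298-3p had 2 and 19, a ratio of 8.16 (1.97 to 72.3), and miR-1264-3p (147010601 to 147010686) had 9 and 28, a ratio of 2.67 (1.23 to 6.44). miR-1912-3p (147009441 to 147009527) had 0 and 11 reads and was at least 3.15-fold higher on a floor of 3 counts over the group. In the induced libraries of trials 1, 2 and 3 the reads were 425, 137 and 98 for miR-1298-5p, 64, 23 and 10 for miR-448-3p, 17, 8 and 3 for miR-1264-3p and 6, 4 and 1 for miR-1912-3p, highest in trial 1 and lowest in trial 3, whereas miR-1298-3p had 6, 3 and 10. Of these only miR-1298-5p was abundant enough for that test. They were picked by name, and other arms or any further hairpins within Htr2c were not examined.

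Among called microRNAs under 10 CPM, miR-449a-5p, from an intron of the cell-cycle gene Cdc20b and known from multiciliated cells, rose by 1.32 on the log2 scale (SE 0.24, edgeR adjusted p = 0.013, n = 3 per group), and its neighbour miR-449c-5p, which did not pass, had 0.97 (SE 0.25). miR-1968-5p and miR-7015-3p rose by 1.78 (SE 0.30) and 1.27 (SE 0.32). miR-129-2-3p fell by 1.92 (SE 0.30), miR-6481 by 1.64 (SE 0.42) and miR-365-1-5p, whose hairpin lies beside that of miR-193b on chromosome 16, by 1.32 (SE 0.33). When 1 library was left out, miR-129-2-3p kept its call in all 6 fits, and the others lost it, with the highest adjusted p without uninduced replicate 1 for miR-1968-5p (0.0614, the only fit that lost it), miR-449a-5p (0.0715, also lost without induced replicate 2) and miR-365-1-5p (0.189), without uninduced replicate 2 for miR-6481 (0.183) and without induced replicate 2 for miR-7015-3p (0.153). The last 3 held without uninduced replicate 3, and miR-6481 also without induced replicate 3. The balance between the arms of a hairpin was compared in 87 hairpins with at least 10 CPM in each arm. With limma 0 passed and 1 had an unadjusted p under 0.05. With the trial as a block 4 passed (miR-98, miR-212, miR-210 and miR-466c, whose 3p arm shares its reads with other entries), the widest being miR-210, whose log2 ratio of the 5p to the 3p arm increased by 1.01 (SE 0.11 blocked, 0.57 unblocked). Across these hairpins, which are not independent replicates, the log2 changes of the arms correlated with Pearson's r 0.862 and Spearman's rho 0.687.

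The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. With edgeR, 1 of them, the real one, gave as many as 32 microRNAs, and the highest count of the others was 0. At an unadjusted p under 0.05 the real split had 109 microRNAs and the others 1 to 67. The 3 other splits that part all 3 pairs gave 0 microRNAs with or without the block, with 1 to 10 at an unadjusted p under 0.05 without it, and the remaining 6 part 1 pair each. Other tools were not run on the splits.

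Libraries of the same trial deviated together. Unequal depth is argued against, since after thinning all libraries to 8697384 reads the lowest of the 3 same-trial correlations was still 0.308. Without the 5 most abundant microRNAs the lowest same-trial correlation was 0.311. This cannot decide whether a few microRNAs taking most of the counts are the source. They would act on the others through a common scaling of a library, which hardly changes a correlation across microRNAs. A shared culture, day or library preparation may be the source, which stays open because the labels give only the trial number.

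Hairpins close to each other, which are not independent replicates, tended to change alike. Over 207 pairs on the same strand within 10 kb (103 hairpins), a rank score of the log2 changes was 0.496. The permuted 95th percentile was 0.126 and the permutation p 0.0001, the smallest that 10000 permutations can give. This score is the mean product of the centred ranks of a pair, divided by the mean squared centred rank of all 329 placed hairpins. Each hairpin was represented by the more abundant of its tested arms placed at 1 hairpin only. Reads shared between similar hairpins are argued against as the cause, since 109 pairs without a shared stretch of 12 bases gave 0.740, also with a permutation p of 0.0001. A first version of both tests, which kept microRNAs with several precursor entries, gave 0.457 over 256 pairs and 0.699 over 121 pairs, with the same p. Transcripts carrying several hairpins stay open, since primary transcripts were not measured and the score on the same strand is the pattern itself. In it, 66.2% of the 207 pairs shared their sign and 6 of 32 clusters went both ways. The largest clusters, of 12 and 13 hairpins within Sfmbt2, were among those that went both ways. They supply many of the 207 pairs, so the score and the shared signs weigh this locus heavily.

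Epithelial markers had a mean log2 change of 1.03 (SE 0.14 over 6 arms from 2 clusters, which are not independent), all 6 being also detected in uninduced cells, but 3 of 6 passed edgeR, 2 DESeq2 and 1 limma-voom, and the list's camera adjusted p was 0.166 with an estimated correlation and 0.474 with the block as well. A lower share of the main cell type would raise the markers of every other type alike. The stromal, lymphoid and liver markers had mean changes of -0.52, -0.22 and -0.36 (the highest being -0.223). These lists cannot decide, because miR-181a-5p of the lymphoid and miR-192-5p of the liver list averaged 28918 and 15333 CPM. Such levels may come from the main cells, whose lower share would not raise them. The stromal list counts miR-199a-3p and miR-199b-3p, 1 measurement, as 2 members. The erythroid miR-486a-5p and miR-486b-5p, also 1 measurement, had a mean of 0.34, and the 2 neural members 0.09. The neural miR-9-5p, too rare to test, had 11 reads uninduced and 38 induced. A lower share of the main cell type therefore stays open. Epithelial cells or their RNA in the induced cultures could add such reads and stay open, since miR-203-3p and miR-205-5p, too rare to test, had 25 reads induced and 5 uninduced, a ratio of 4.30 (95% exact interval 1.62 to 14.4). The most abundant markers reached only 58.8 CPM (miR-141-3p) and 18.4 CPM (miR-200c-3p), and no label names a sort that would remove such cells. A change within the iBN cells on induction, or an effect of doxycycline itself, was not tested and stays open too.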
